A study of Mus musculus with 4 samples.

How the data were processed

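RNA-seq libraries of mouse CD4+ T cells, cultured for 3 days under Th17-inducing cytokines, were compared by culture temperature (37 or 39.5 °C) and genotype label (wild type or Smad4 knockout), with 1 library in each of the 4 groups. Groups were taken from the genotype and treatment labels. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEXTflex kit; strandedness is not given in the sources used here. Per the submitters' processing notes, the tools were Trim Galore 0.4.4, Bowtie2, featureCounts, Subread and edgeR, and the genome build was mm10, with no order or settings. The annotation release and any filter on genes are not given in the sources used here.

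The authors deposited 1 table per library in RPKM (reads per kilobase of exon, scaled to library size), with 19555 rows in the same order in each. No row was at 0 in every library. RPKM values are already scaled to library size and exon length, so a count test was not used as the main test, and the tests set out beforehand for deposited counts were not run. Spliced reads can be lost by an aligner that does not split reads over introns, which would lower genes with many short exons in every library alike. The values carry whole reads: multiplied by exon length and library size they fall on whole numbers. Of 13172 rows that matched a gene name in GENCODE vM21, 12071 (91.6%) were whole in all libraries at that annotation's exon length, with a tolerance of 0.01 reads. Allowing each row its own length, whole reads were recovered for 19554 of the 19555 rows within 0.003 reads, and 19487 rows (99.7%) held 10 or more reads in all. On simulated tables the recovery gave the true reads for 98.4% of 1999 rows. The library sizes behind the RPKM values were 18216613, 19308699, 17639131 and 18410930 in WT at 37 and 39.5 °C and in the libraries labelled Smad4 KO at 37 and 39.5 °C. Divided by the reads recovered in each library (18074376, 18282037, 18506085 and 18503228) they gave 1.01, 1.06, 0.953 and 0.995, so the deposited values carry a scaling factor other than total reads. Rows at 0 numbered 180, 112, 156 and 142.

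Values were analysed as log2(RPKM + 1) for the 13715 rows with a mean of at least 1 RPKM. Each pair of libraries was compared by the log2 ratio, with a size rule of 2-fold and no p-value. The difference in temperature response between genotypes was the difference of 2 log2 ratios, and for a list the median of its members' differences. For named genes, ratios of RPKM are given with exact Clopper-Pearson 95% intervals, conditional on the summed recovered reads of the pair; PCR reads without molecular identifiers are not independent molecules, so intervals and the floor of 3 reads for a library at 0 cover counting error only. Changes shared by both genotypes or both temperatures were tested with limma 3.58.1 in R 4.3.3 (additive model of genotype and temperature, empirical Bayes with a trend, 1 residual degree of freedom, Benjamini-Hochberg adjusted p under 0.05). The interaction serves as the residual there, and empirical Bayes draws it towards a trend over all genes. The prior degrees of freedom had a median of 4.475, against 1 residual degree of freedom. A gene whose temperature change depends on genotype has a raised error but can still pass, so a call does not show equal changes in both pairs. Nothing in the labels says whether the libraries came from separate animals or culture days. The p-values set a change against that interaction and the trend over all genes in these libraries, not against a spread between animals or cultures. A condition common to both cultures of a genotype or of a temperature is not part of that error. In simulations with a spread of 10% and 200 changed genes among 13715, the shared temperature test called 97% of 2-fold and 100% of 4-fold changes and 19 unchanged genes, and 4 genes for genotype when no genotype change was simulated. Every simulated gene had the same spread and the same temperature change in both genotypes, which real genes need not have. These shares are therefore not the power of the test in the data, where it called 3 genes for temperature. Counting noise alone put 0 simulated genes past the 2-fold rule for temperature in WT and 1 for the difference between genotypes. Simulated gene lengths were drawn at random and not taken from the rows, so that count does not cover very short genes such as mt-Tg.

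Gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined. There were 29 lists: heat shock, cold-inducible, ER stress, core Th17, pathogenic and non-pathogenic Th17, Th1, Th2, Treg, Tfh, TGF-β and SMAD targets, STAT targets, SUMO pathway, cell cycle, glycolysis, OXPHOS, cholesterol synthesis, interferon response, p53 and apoptosis, naive and memory, T cell identity, CD8 and NK, B cell, myeloid, erythroid and platelet, ribosomal protein, mitochondrially encoded, histone and nuclear non-coding RNA genes. The list of STAT targets, called the STAT list below, also holds genes of cytokines and receptor chains, such as Il2, Il6ra and Il6st. Each list with at least 3 measured members was described by its median and its percentile among 10000 random lists. The random lists were matched on mean expression in 20 bins. In simulations 6.5% of unchanged lists fell outside the central 95%. Simulated genes varied independently, while members of a real list can vary together, so that share does not carry over to these lists. In the shared tests members were counted both over all genes and adjusted over the list alone. A list of hypoxia-inducible factor targets that shares no gene with the glycolysis list was added after the data were seen, and later a shorter form without Pfkfb3, Pfkfb4, Pgm1 and Pgm2.

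Genes were named by rule: 28 genes, Smad4 first, whatever their values, the 10 genes with the largest change in each direction common to both pairs for temperature and for genotype, the 10 highest and 10 lowest differences between genotypes, and up to 4 list members with the largest change in the comparison described. Members that passed a test are named beyond those 4 where a count is spelled out, which was chosen after their values were seen. Predicted genes, small RNAs, pseudogenes and antigen receptor segments were left out of the ranked names. Clone-based names (6117 rows) and 20 date-like names, which a spreadsheet makes from symbols such as those of the septin genes, were left out as well, a class the rule had not named. Of the 28 genes, 27 were found, and Ifng was not analysed here. Some genes that meet the rule are not reported here. Coordinates are those of GENCODE vM21 on GRCm38, the assembly that mm10 also names.

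Alternatives changed 1 choice at a time: a pseudocount of 0.1 or 5, no filter or a minimum mean of 5 RPKM, rescaling by a trimmed mean of M-values (written for this work without weights, trimming 30% of ratios and 5% of levels on each side) or by the upper quartile, a 1.5-fold rule, Spearman's correlation and limma without a trend. One alternative was added after seeing the data, limma-voom on the recovered reads. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.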

Results

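Naive CD4+ T cells from spleen and lymph nodes of C57BL/6 mice were differentiated in culture with IL-6 and transforming growth factor β1 (TGF-β1), the cytokine pair that drives T helper 17 (Th17) differentiation, and their RNA was sequenced after 3 days. The cultures differed in temperature, 37 °C or the fever-range 39.5 °C, and in genotype, wild type (WT) or knockout (KO) of Smad4, which encodes the common partner of the receptor-activated SMAD proteins in TGF-β signalling. The questions were whether fever-range heat alters the Th17 transcriptome and whether that response depends on Smad4. Each of the 4 combinations of temperature and genotype had 1 library, so no ratio between a pair of libraries had a replicate check, and the 95% intervals given for such ratios cover counting error only. Expression was reported as RPKM (reads per kilobase of exon, scaled to library size). Whole reads recovered from the RPKM values summed to 18074376 in the WT library at 37 °C, 18282037 in the WT library at 39.5 °C, 18506085 in the library labelled Smad4 KO at 37 °C and 18503228 in the library labelled Smad4 KO at 39.5 °C.

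Smad4 itself was examined before any comparison, because its level bears on the genotype labels. It stood at 14.0 RPKM in WT at 37 °C (950 reads) and 14.2 RPKM in WT at 39.5 °C (1016 reads), against 20.7 RPKM (1357 reads) and 21.3 RPKM (1458 reads) in the libraries labelled Smad4 KO at 37 and 39.5 °C. The ratio of the library labelled Smad4 KO to WT was 1.48 (95% interval 1.36 to 1.60) at 37 °C and 1.51 (1.39 to 1.63) at 39.5 °C, so the targeted gene was higher, not lower, in both libraries carrying the KO label. Smad4 lies on chromosome 18, positions 73639009 to 73703780 on the minus strand of GRCm38. An RPKM summed over all exons cannot show the loss of part of a gene, and which exons were deleted is not given in the sources used here. The genotype direction in everything that follows is that of the label. Of the partner genes, Smad3 rose with the KO label at both temperatures in a limma fit of all libraries (25.0, 19.4, 41.9 and 29.9 RPKM in WT at 37 and 39.5 °C and in the libraries labelled Smad4 KO at 37 and 39.5 °C; log2 0.66 ± 0.12 SE, adjusted p = 0.031). Smad2 did not pass the test (log2 −0.41 ± 0.12, adjusted p = 0.081).

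In WT cells the signature Th17 cytokine genes were higher at 39.5 °C. Il17a (chromosome 1, 20730905 to 20734496) went from 134 to 686 RPKM, a ratio of 5.11 (4.91 to 5.32), and its neighbour Il17f (20777146 to 20790617) from 516 to 1338 RPKM, a ratio of 2.59 (2.55 to 2.64). The IL-23 receptor gene Il23r stood at 2.25 and 6.66 RPKM at 37 and 39.5 °C, and Il21 at 54.2 and 94.4 RPKM. The chemokine gene Ccl3 was at 0.932 and 16.2 RPKM, and Il9 at 10.5 and 42.8 RPKM. Cdkn1a, which encodes the cell cycle inhibitor p21, had a ratio of 7.98 (7.45 to 8.56), from 22.3 to 178 RPKM. On the low side were the chaperone gene Hspa8 (795 to 307 RPKM, ratio 0.387, 0.381 to 0.392) and the matrix metalloproteinase gene Mmp13 (14.95 to 1.98 RPKM). Of 13715 rows with a mean of at least 1 RPKM over the 4 libraries, 200 were at least 2-fold higher and 72 at least 2-fold lower at 39.5 °C on the log2(RPKM + 1) scale, which understates the change of low genes. The median log2 ratio of all these rows was −0.02.

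In the libraries labelled Smad4 KO, Il17a and Il17f were also higher at 39.5 °C, by smaller ratios than in WT. Il17a stood at 32.6 RPKM at 37 °C and 79.7 RPKM at 39.5 °C, a ratio of 2.45 (2.24 to 2.68), and Il17f at 205.8 and 292 RPKM, a ratio of 1.42 (1.38 to 1.46). Il23r was at 1.53 and 4.13 RPKM and Il9 at 1.59 and 9.22 RPKM. Il21 was at 65.6 and 61.2 RPKM and Cdkn1a at 137 and 130.3 RPKM. Hspa8 was again lower, at 466 and 245 RPKM. Il10 had 32 reads at 37 °C and 0 at 39.5 °C, which was at least 11.1-fold lower with 3 reads as the floor for the library at 0. The counts at the 2-fold rule were 103 genes higher and 125 lower at 39.5 °C, with a median log2 ratio over all rows of −0.01.

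**Figure D1:**
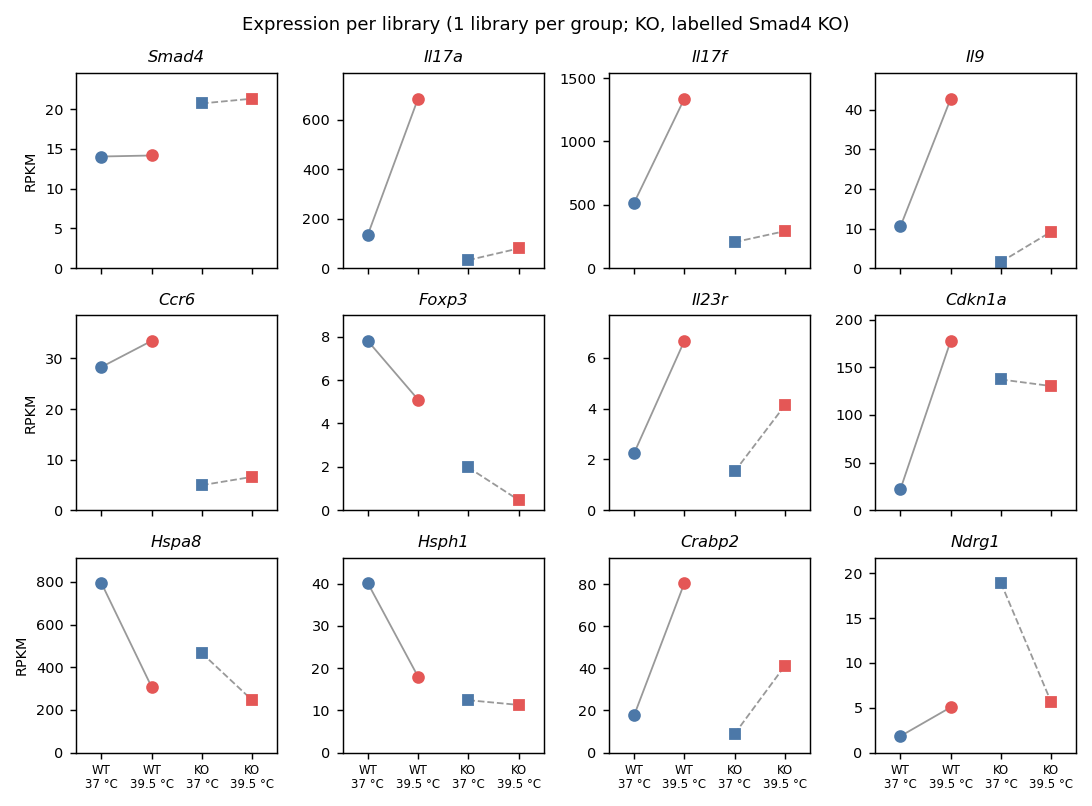
Expression in RPKM (vertical axes, from 0) of 12 genes in the 4 libraries, 1 point per library, with circles for WT, squares for libraries labelled Smad4 KO, blue for 37 °C and red for 39.5 °C. Smad4 lies higher in both libraries labelled Smad4 KO (20.7 and 21.3 RPKM) than in WT (14.0 and 14.2 RPKM), and Il17a is highest in WT at 39.5 °C (686 RPKM).

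The temperature responses of the 2 genotypes were compared across genes; the pairs share no library. Across the 13715 genes, which are not independent replicates, Pearson's r of the temperature log2 ratios was 0.39 and Spearman's rho 0.32. Among the 432 genes at least 2-fold changed in either pair, 343 (79.4%) differed in the same direction in both, against 60.5% of all 13715 genes. The 200 genes at least 2-fold higher in WT had a median log2 ratio of 1.24 there and 0.56 in the libraries labelled Smad4 KO, where 46 of them were also at least 2-fold higher. The 72 genes at least 2-fold lower in WT had medians of −1.19 and −0.71, and 19 were also at least 2-fold lower in the other pair. Chosen in the other direction, the 103 genes higher in the libraries labelled Smad4 KO had medians of 1.23 there and 0.75 in WT, and the 125 lower genes had −1.30 and −0.23. A set picked in one pair is expected to sit closer to 0 in the other, since selection favours chance values in the pair it was picked in.

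**Figure D2:**
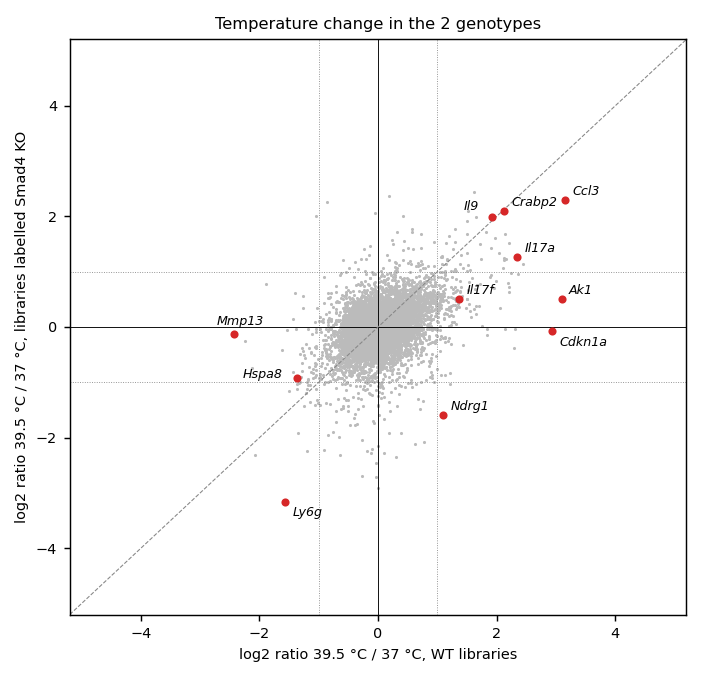
Each grey point is 1 of 13715 genes, with the log2 ratio of RPKM + 1 at 39.5 °C to 37 °C in WT on the horizontal axis and in the libraries labelled Smad4 KO on the vertical axis; dotted lines mark 2-fold and the dashed line marks equality. Crabp2 and Il9 lie near the dashed line, while Cdkn1a sits at 2.94 and −0.07.

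Genes that moved with temperature in both genotypes were sought with an additive limma fit of the 4 libraries, in which 2 libraries stand at each temperature. With Benjamini-Hochberg adjustment, 3 genes passed, among them Crabp2 and Il9. Crabp2, which encodes a retinoic acid binding protein, rose (log2 2.11 ± 0.12 SE; 17.6, 80.6, 8.88 and 41.3 RPKM in WT at 37 and 39.5 °C and in the libraries labelled Smad4 KO at 37 and 39.5 °C), and Il9 rose (1.95 ± 0.12), each with an adjusted p of 0.041 and the same direction in both genotypes. At unadjusted p under 0.05 there were 983 genes higher and 931 lower. Il17a had a shared log2 change of 1.80 ± 0.26 and Il17f of 0.94 ± 0.21, with adjusted p of 0.091 and 0.164. Beyond Crabp2, Il9 and Ccl3, the genes with the largest increase found in both pairs were Bdh2, Angptl2, Spp1, Gstt3, Zbtb32, Nrp1 and Tm4sf5. For example, Spp1, which encodes osteopontin, stood at 3.73, 13.8, 6.09 and 27.2 RPKM in the same library order, and the semaphorin receptor gene Nrp1 at 0.870, 7.59, 0.330 and 2.83 RPKM. Among the largest decreases in both pairs were those in Ly6g, Gpr83, Aldoc, Vegfa, Selp, Lingo3, Ighm, Rgcc and Zdhhc23; Vegfa, the vascular endothelial growth factor gene, was at 7.32, 2.56, 18.1 and 7.29 RPKM. This fit had 1 residual degree of freedom per gene, and its count ranged from 0 without a variance trend to 350 with limma-voom on the recovered reads.

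Among gene lists fixed before the data were examined, the core Th17, pathogenic Th17 and Th1 lists stood on the high side at 39.5 °C in both genotypes. The Th1 medians depended on the minimum mean. The non-pathogenic Th17, Th2 and Tfh lists were not on the high side in both genotypes. The 17 measured core Th17 genes had a median log2 ratio of 0.47 in WT and 0.35 in the libraries labelled Smad4 KO, each at percentile 100 among 10000 random lists matched on expression. In the limma fit 0 of the 17 passed over all genes, while 6 rose when adjusted over the list alone, among them Il17a, Il1r1, Il23r, Il17f and Ccl20. Genes tied to pathogenic Th17 cells had medians of 0.95 and 0.55 (12 measured, percentile 100 in both), with 7 rising and 2 falling when adjusted over the list alone and 0 over all genes. Those that rose were Ccl3, Ccl4, Cxcl3, Il23r, Tbx21, Lag3 and Ccl5. Csf2, which encodes the cytokine GM-CSF, was at 1.51 and 2.59 RPKM in WT and 3.54 and 3.94 RPKM in the other pair. The non-pathogenic Th17 list had medians of 0.09 and 0.01 (6 measured, percentiles 81.1 and 54.3), and Il9 was its only member that rose, over all genes and over the list alone. Th1 genes had medians of 0.79 and 0.72 (7 measured, percentile 100 in both), with 5 rising and 2 falling when adjusted over the list alone. With a minimum mean of 5 RPKM these Th1 medians turned to −0.18 and −0.53. Th2 genes had medians of 0.38 and 0.14 (5 measured, percentiles 98.7 and 85.8), with Gata3 and Ccr8 rising when adjusted over the list alone. Tfh genes had 0.02 and 0.23 (7 measured, percentiles 53.1 and 98), with Pdcd1, the gene of the inhibitory receptor PD-1, rising when adjusted over the list alone. Apart from Il9, 0 members of these lists passed over all genes.

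Proliferation and p53 target genes were higher at 39.5 °C too. The cell cycle list had medians of 0.64 in WT and 0.44 in the libraries labelled Smad4 KO (27 measured, percentile 100 in both), and 18 members rose when adjusted over the list alone, with 0 over all genes. Kif20a, a mitotic kinesin gene, went from 9.52 to 20.8 RPKM in WT and from 10.9 to 18.4 RPKM in the other pair. Histone genes had medians of 0.37 and 0.57 (44 measured, percentile 100 in both), with 7 rising when adjusted over the list alone and 0 over all genes; reads of these near-identical copies are uncertain by gene. The p53 and apoptosis list had medians of 1.10 and 0.29 (16 measured, percentile 100 in both), and 9 members were at least 2-fold higher in WT against 1 in the other pair. When adjusted over the list alone, 7 rose, among them Phlda3 (14.2 to 65.1 RPKM in WT, 19.9 to 47.3 RPKM in the libraries labelled Smad4 KO) and Bbc3, which encodes the pro-apoptotic protein PUMA (5.22 to 18.4 and 11.8 to 19.4 RPKM). Over all genes 0 passed.

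Chaperone and secretory stress genes were not on the high side at 39.5 °C after 3 days. Heat shock genes, the targets of the heat-activated factor HSF1, had a median of −0.26 in WT (19 measured, percentile 0.27), with 17 members below 0 and 2 above. In the libraries labelled Smad4 KO the median was −0.0020 (percentile 63.5). In the limma fit 0 passed over all genes, and Hspa8 fell when adjusted over the list alone (log2 −1.15 ± 0.14). Hsph1, which encodes HSP110, was at 40.2 and 18.0 RPKM in WT and 12.4 and 11.3 RPKM in the other pair; Dnajb1 was at 44.4 and 30.2, then 41.0 and 34.3 RPKM. The inducible HSP70 genes Hspa1a and Hspa1b, near-identical copies whose reads are uncertain by gene, reached at most 0.703 and 1.35 RPKM in any library. Hsf1 was at 14.4 and 13.3 RPKM in WT and 12.0 and 15.3 RPKM in the libraries labelled Smad4 KO. ER stress genes had medians of −0.52 and −0.70 (20 measured, percentile 0 in both), with 15 falling and 1 rising when adjusted over the list alone and 0 over all genes. Creld2 went from 63.3 to 30.9 and from 79.9 to 30.3 RPKM, and Sdf2l1, which encodes an ER chaperone partner, from 137 to 71.7 and from 190.5 to 105 RPKM. The cold-inducible genes Cirbp (8.88 and 10.3, then 9.88 and 10.4 RPKM) and Rbm3 (29.2 and 26.8, then 29.3 and 23.2 RPKM) are too few for a percentile, and 0 passed.

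Metabolic genes differed in their response. Cholesterol synthesis genes had medians of −0.51 in WT and −0.16 in the libraries labelled Smad4 KO (21 measured, percentiles 0 and 0.80), with Lss and Mvd falling when adjusted over the list alone. Glycolysis genes had −0.22 and −0.43 (17 measured, percentiles 5.30 and 0), with 7 falling when adjusted over the list alone, among them the glucose transporter gene Slc2a1 (73.3 to 43.0 and 188 to 121 RPKM). Nuclear genes of oxidative phosphorylation had −0.07 and −0.04 (30 measured, percentiles 74.7 and 32.2), and mitochondrially encoded genes 0.22 and 0.11 (32 measured, percentile 100 in both, 4 rising and 2 falling when adjusted over the list alone). Treg genes had −0.03 and −0.77 (9 measured, percentiles 66.9 and 0), with 1 rising and 4 falling when adjusted over the list alone. Foxp3, the Treg lineage factor gene, was among those that fell (7.80 to 5.10 and 1.98 to 0.477 RPKM). The IL-6 and IL-2 STAT list had 0.14 and −0.29 (15 measured, percentiles 99.9 and 0.07), with Pim2 and Bcl3 falling when adjusted over the list alone. TGF-β and SMAD target genes had 0.14 and −0.01 (16 measured, percentiles 98.7 and 52.6). SUMO pathway genes had 0.11 and 0.09 (17 measured, percentiles 98.3 and 88.7), interferon response genes 0.11 and 0.07 (10 measured, percentiles 78.1 and 78.6), naive and memory genes 0.05 and −0.04 (13 measured, percentiles 92.6 and 32.7), T cell identity genes 0.07 and −0.03 (13 measured, percentiles 99.9 and 67.8), ribosomal protein genes −0.14 and −0.13 (79 measured, percentiles 35.5 and 0.465) and nuclear non-coding RNAs 0.01 and −0.14 (3 measured, percentiles 64.3 and 21.3). In the naive and memory list 1 member passed, over all genes and when adjusted over the list alone; in the other lists of this paragraph 0 passed over all genes. In the OXPHOS, TGF-β and SMAD, SUMO, interferon, T cell identity, ribosomal protein and non-coding RNA lists 0 members passed either way. A percentile places a list within these libraries and is not a test.

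Il17a and Il17f were lower in the libraries labelled Smad4 KO at both temperatures. That direction rests on the label. Total Smad4 expression was higher with the KO label and cannot settle whether the label is right. At 37 °C the ratio to WT was 0.243 (0.223 to 0.264) for Il17a and 0.399 (0.388 to 0.410) for Il17f; at 39.5 °C it was 0.116 (0.111 to 0.122) and 0.218 (0.214 to 0.223). The chemokine receptor gene Ccr6, a Th17 surface marker, was at 28.3 and 4.98 RPKM at 37 °C and 33.5 and 6.62 RPKM at 39.5 °C, for WT and the library labelled Smad4 KO. Foxp3 was at 7.80 and 1.98, then 5.10 and 0.477 RPKM. Higher in the libraries labelled Smad4 KO were Lrrc32, which encodes the latent TGF-β carrier GARP (1.99 and 61.6, then 0.674 and 15.1 RPKM), the integrin gene Itga7 (1.11 and 58.8, then 0.128 and 11.8 RPKM), the glucose transporter gene Slc2a3 (7.05 and 111, then 3.77 and 29.0 RPKM) and Oas3 (0.217 and 6.91, then 0.271 and 7.63 RPKM). Olfm2 had 125 reads in WT at 37 °C and 0 in the library labelled Smad4 KO, which was at least 40.3-fold lower against the floor of 3 reads. At 37 °C, 645 genes were at least 2-fold higher and 156 lower with the KO label, and at 39.5 °C 315 were higher and 144 lower. The medians of all rows were −0.01 and 0.00.

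Across genes the genotype differences at the 2 temperatures had a Pearson's r of 0.71 and a Spearman's rho of 0.67, from pairs that share no library. Of 987 genes at least 2-fold different at either temperature, 931 (94.3%) differed in the same direction at both, against 75.3% of all 13715 genes. The 645 genes higher at 37 °C had a median log2 ratio of 1.28 there and 0.89 at 39.5 °C, with 226 also at least 2-fold higher. Of the 156 lower genes, 42 were also at least 2-fold lower at 39.5 °C (medians −1.19 and −0.69).

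**Figure D3:**
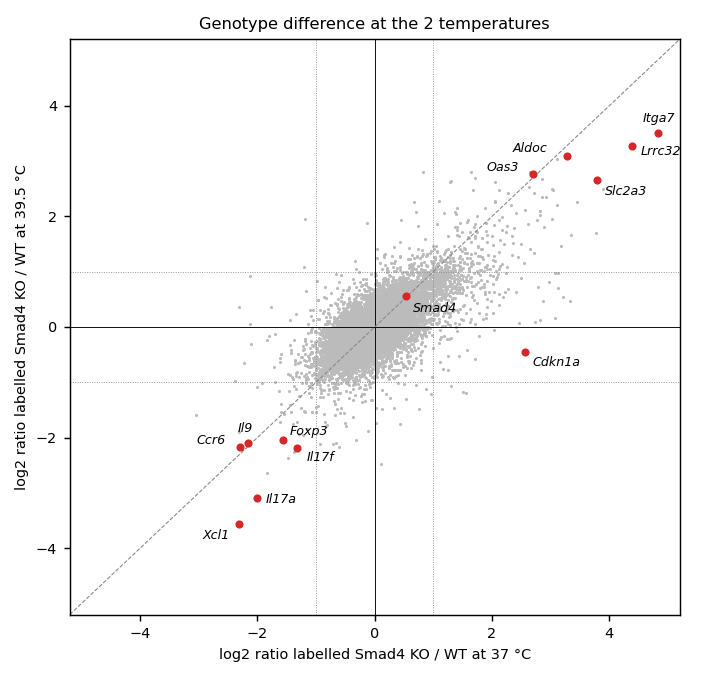
Each grey point is 1 of 13715 genes, with the log2 ratio of RPKM + 1 in the library labelled Smad4 KO to WT at 37 °C on the horizontal axis and at 39.5 °C on the vertical axis; dotted lines mark 2-fold and the dashed line marks equality. Smad4 lies above 0 on both axes (0.53 and 0.56), Il17a below 0 on both (−2.01 and −3.09), and Cdkn1a at 2.57 and −0.44.

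In the additive limma fit, 1820 genes differed with the genotype label at an adjusted p under 0.05, 1176 rising and 644 falling in the libraries labelled Smad4 KO. Smad4 was among those that rose (log2 0.54 ± 0.12 SE, adjusted p = 0.045), a call that was lost without a variance trend and with upper quartile scaling. The largest increases found at both temperatures were in Itga7 (log2 4.16 ± 0.31, adjusted p = 0.0078), Lrrc32 (3.83 ± 0.27, adjusted p = 0.0074), Aldoc, Ifitm2, Oas3, Asb2, Slc2a3, Lgals7, F2rl1 and Upp1, all of which passed with adjusted p from 0.0054 to 0.010. Decreases were ranked, like the increases, by the smaller of the log2 ratios at 37 and 39.5 °C, not by the fitted value. The largest were in Xcl1 (−2.94 ± 0.30, adjusted p = 0.014), Ccr6 (−2.24 ± 0.12, adjusted p = 0.0062), Il9 (−2.13 ± 0.12, adjusted p = 0.0062) and Il17a (−2.55 ± 0.26, adjusted p = 0.014). The others were Olfm2, Ccr8, mt-Te, Foxp3 (−1.81 ± 0.17, adjusted p = 0.012), mt-Nd6 and Plek, and all of these genes also passed. Il17f fell (−1.76 ± 0.21, adjusted p = 0.015). Csf2 did not pass (0.66 ± 0.16, adjusted p = 0.054). Il2ra, the gene of the high-affinity IL-2 receptor chain CD25, was at 306 and 394 RPKM at 37 °C and 299 and 259 RPKM at 39.5 °C. Without the filter on low values, 0 genes passed, and the smallest adjusted p was 0.055.

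Glycolysis genes rose with the KO label almost as a whole list. Of 17 measured members, 15 rose over all genes and 17 when adjusted over the list alone, and the median log2 ratio was 0.86 at 37 °C and 0.73 at 39.5 °C (percentile 100 in both). Slc2a1 rose by log2 1.41 ± 0.12 (adjusted p = 0.0098), the lactate and pyruvate transporter gene Slc16a3 by 1.29 ± 0.15 (adjusted p = 0.015) and the phosphoglycerate kinase gene Pgk1 from 142 to 320.1 RPKM at 37 °C and from 122 to 231 RPKM at 39.5 °C. Interferon response genes had medians of 0.69 and 0.69 (10 measured, percentile 100 in both), with 5 rising over all genes and 7 when adjusted over the list alone. Those 5 were Oas3, Isg15 (log2 1.66 ± 0.14), Ddx58, Irf7 and Irf9. OXPHOS genes had medians of 0.10 and 0.13 (30 measured, percentiles 79.4 and 67.7), with 1 falling over all genes, Cycs, and 0 when adjusted over the list alone.

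Core Th17 genes moved both ways with the KO label: 8 of 17 fell and 2 rose over all genes, and 10 fell and 3 rose when adjusted over the list alone. The medians were −0.57 at 37 °C and −0.62 at 39.5 °C (percentile 0 in both). Beside Il17a, Il17f and Ccr6, the fallen genes were Il1r1, the Th17 factor gene Rora (log2 −1.30 ± 0.16), Batf (−1.10 ± 0.14), Tmem176a and Tmem176b. The leukotriene receptor gene Ltb4r1 (2.32 ± 0.39) and Ccl20 rose. Non-pathogenic Th17 genes had medians of −0.90 and −0.90 (6 measured, percentile 0 in both), with Il9, Ikzf3 and Il6st falling over all genes and 5 falling and 1 rising when adjusted over the list alone. Pathogenic Th17 genes had −0.04 and −0.31 (12 measured, percentiles 40.5 and 0.77), with Ccl5 rising and Ccl3 falling over all genes and 3 each way when adjusted over the list alone. Il22 stayed under 1 RPKM in all 4 libraries, at most 0.467 RPKM in WT at 39.5 °C, so its difference was not tested in the main fit. Il10 was at 2.10 RPKM in both WT libraries, 1.38 RPKM in the library labelled Smad4 KO at 37 °C and 0 reads at 39.5 °C, where it was at least 16.8-fold lower than WT.

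Genes of other T helper fates also moved both ways. Of 9 Treg genes, 4 rose and 2 fell over all genes and over the list alone: Lrrc32, Izumo1r (log2 2.26 ± 0.12), Tnfrsf18 and Gpr83 rose, while Foxp3 and Nt5e fell, and the medians were 0.39 and 0.08 (percentiles 97.3 and 52.3). The Th1 genes Il12rb2 (1.94 ± 0.22), Ccl5 and Runx3 rose, 3 of 7 over all genes and over the list alone (medians 0.54 and 0.19, percentiles 99.2 and 90.3). Tbx21, which encodes T-bet, was at 0.419 and 0.501 RPKM at 37 °C and 1.46 and 1.81 RPKM at 39.5 °C. The Th2 list had medians of 0.29 and −0.08 (5 measured, percentiles 86.8 and 31.7), with Il4 rising and Ccr8 falling over all genes and over the list alone. The Tfh list had −0.74 and −0.23 (7 measured, percentiles 0 and 11), with Cxcr5 and Pdcd1 falling over all genes and 4 falling and 1 rising over the list alone. Naive and memory genes had 0.19 and 0.26 (13 measured, percentiles 90.0 and 94.8); 3 rose and 1 fell over all genes, among them Klf2 (2.02 ± 0.14), Lef1 and the fallen Bach2, and 6 rose and 2 fell when adjusted over the list alone.

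Signalling and stress lists completed the genotype comparison. TGF-β and SMAD target genes had medians of 0.28 and 0.05 (16 measured, percentiles 97.2 and 55.8), with Smad7 (log2 0.59 ± 0.13), Junb and Tgfb1 rising and Tgfbr1 (−0.91 ± 0.16) and Id1 falling over all genes and over the list alone. The STAT list had 0.53 and 0.18 (15 measured, percentiles 100 and 73.0). Over all genes Socs3, Socs1, Pim2, Cish and Bcl3 rose. The cytokine gene Il2 (−1.49 ± 0.13) and the receptor chain gene Il6st fell. When adjusted over the list alone, 6 rose and 2 fell. Heat shock genes had −0.66 and −0.41 (19 measured, percentile 0 in both): 6 fell over all genes and 13 when adjusted over the list alone, among them Hsph1 (−1.12 ± 0.24), Hsp90aa1 (52.3 and 26.7 RPKM at 37 °C, 47.4 and 26.5 RPKM at 39.5 °C) and Cacybp. ER stress genes had 0.31 and −0.05 (20 measured, percentiles 98.6 and 9.35), with Trib3, Xbp1 and Sdf2l1 rising over all genes and 4 when adjusted over the list alone. SUMO pathway genes had −0.26 and −0.18 (17 measured, percentiles 2.19 and 2.67), with the SUMO protease gene Senp6 falling over all genes and over the list alone. Cholesterol synthesis genes had 0.02 and 0.34 (21 measured, percentiles 64.8 and 99.9), with Idi1 falling over all genes and over the list alone. The p53 and apoptosis list had 0.12 and −0.40 (16 measured, percentiles 85.8 and 0), with Bcl2 rising over all genes and 0 members when adjusted over the list alone. The cell cycle list had −0.14 and −0.19 (27 measured, percentiles 6.96 and 0.15) and the histone list −0.13 and −0.05 (44 measured, percentiles 6.65 and 44.5), and 0 members of either passed.

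Markers of RNA content and of other cells were read beside these lists. Mitochondrial transcripts took 2.53% and 2.94% of the recovered reads in WT at 37 and 39.5 °C, and 1.79% and 1.83% in the libraries labelled Smad4 KO. The mitochondrially encoded list fell with the KO label, with medians of −0.61 and −0.68 (32 measured, percentile 0 in both), 19 members falling over all genes and 23 when adjusted over the list alone. mt-Nd5 was at 692 and 308 RPKM at 37 °C and 686 and 354 RPKM at 39.5 °C for WT and the library labelled Smad4 KO. mt-Te and mt-Nd6 lie on the minus strand opposite other mitochondrial transcripts, so without knowledge of strand their reads are uncertain by gene. Ribosomal protein genes had medians of 0.25 and 0.25 (79 measured, percentiles 98.1 and 89.8), with 7 rising over all genes and 0 when adjusted over the list alone. Nuclear non-coding RNAs had −0.41 and −0.60 (3 measured, percentiles 6.36 and 0.74), with Gas5 falling over all genes and 3 when adjusted over the list alone. T cell identity genes had 0.19 and 0.31 (13 measured, percentiles 65 and 84.5), with 3 rising, among them Cd2 and Cd3g, and Zap70 falling over all genes and 7 rising and 2 falling when adjusted over the list alone. Cd4 ranged from 192 RPKM in WT at 37 °C to 212 RPKM in the library labelled Smad4 KO at 37 °C. Of the CD8 and NK cell markers, 2 reached a mean of 1 RPKM, Cd8b1 (3.52 and 3.91 RPKM in WT, 4.01 and 2.86 RPKM with the KO label) and Klrd1, and 0 passed. Of the myeloid markers, 2 reached it, Cst3 and the lysosomal gene Cd68, which rose with the KO label (log2 0.74 ± 0.13, adjusted p = 0.028; 1.70 and 4.57 RPKM in WT, 3.61 and 8.17 RPKM with the KO label). Cd68 also rose with temperature when adjusted over the list alone. B cell markers and erythroid and platelet markers had 0 members at a mean of 1 RPKM. The immunoglobulin heavy chain gene Ighm, named above among the decreases with temperature, is on none of these lists. The lists therefore do not exclude a share of other cells. Outside these lists, and chosen after their values were seen, the MHC class II gene H2-Ab1 and the invariant chain gene Cd74, which antigen-presenting cells express, were higher with the KO label: H2-Ab1 at 4.56 and 59.6 RPKM at 37 °C and 3.23 and 19.3 RPKM at 39.5 °C, and Cd74 at 12.7 and 23.3, then 22.6 and 41.7 RPKM.

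**Figure D4:**
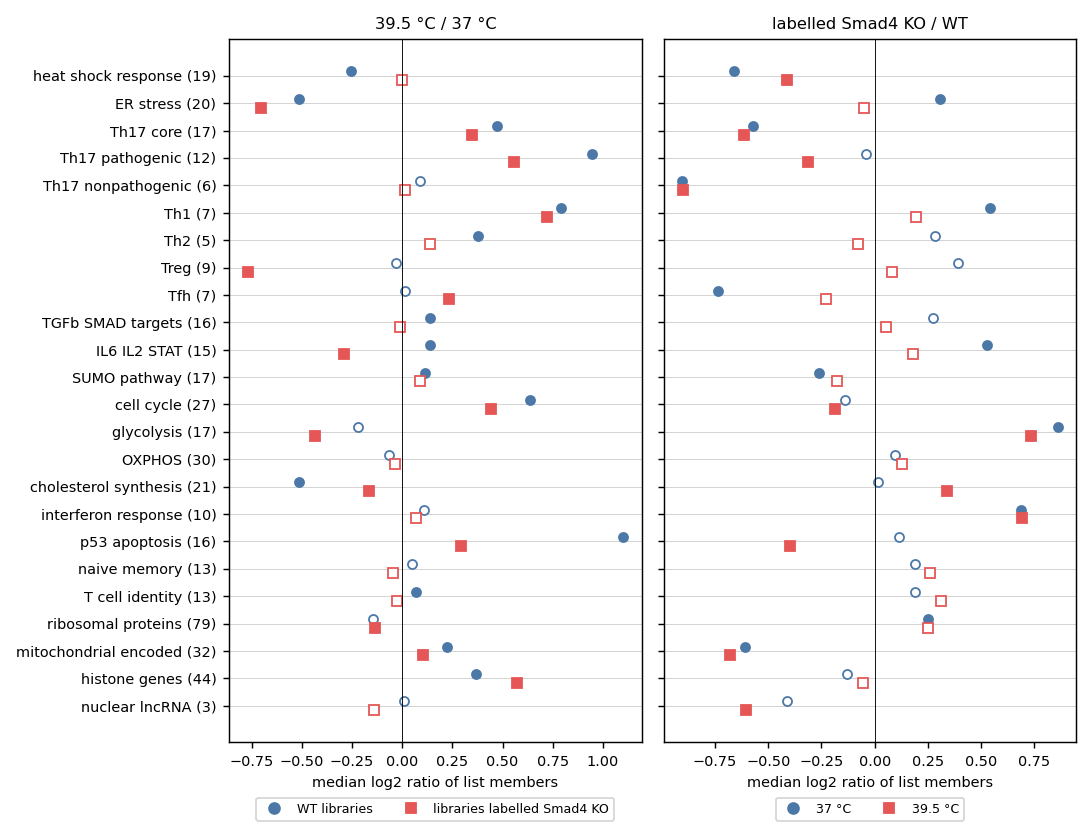
Median log2 ratio of the measured members of each gene list with at least 3 members (number in parentheses), for 39.5 °C to 37 °C in each genotype on the left and for libraries labelled Smad4 KO to WT at each temperature on the right. Filled symbols lie outside the central 95% of random expression-matched lists; the core Th17 list lies right of 0 for temperature (0.47 and 0.35) and left of 0 for genotype (−0.57 and −0.62).

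The last comparison asked whether the temperature change differed between the genotypes, as the log2 ratio in the libraries labelled Smad4 KO minus that in WT. For Il17a the difference was −1.08 and for Il17f −0.87; the counting intervals of the temperature ratios did not overlap for either gene (5.11, 4.91 to 5.32, against 2.45, 2.24 to 2.68, for Il17a). For Il9 it was 0.06 and for Il23r −0.22, on the log2(RPKM + 1) scale, which understates the change of low genes. By the RPKM values themselves, the temperature ratio of Il9 was larger with the KO label than in WT. Among the lowest differences were those in Cdkn1a (−3.01), Basp1 (−2.75), Ndrg1 (−2.69), Selenbp1 (−2.67), Ak1 (−2.59), Tgm1 (−2.44), Cxcr1 (−2.42), Ifitm1 (−2.39) and Il24 (−2.30). With limma-voom on the recovered reads, the shared temperature changes of Selenbp1, Tgm1 and Cxcr1 were log2 −3.4, −3.13 and −3.67. The main fit gave −1.38, −1.25 and −1.48 for them. The voom and main fits gave −2.27 and −1.09 for Ifitm1, −1.65 and −0.77 for Il24, and 4.11 and 1.80 for Ak1. For Cdkn1a they gave 1.49 and 1.43. The differences of Selenbp1, Tgm1, Cxcr1, Ifitm1 and Il24 therefore cannot be told apart from an effect of low values. The size of the Ak1 change likewise depends on how low values are treated. Ak1 was at 0.191 and 9.17 RPKM in WT and 0.284 and 0.817 RPKM with the KO label. Ndrg1 was at 1.83 and 5.05, then 18.9 and 5.60 RPKM. The highest differences were in Mmp13 (2.29), mt-Tg (2.13), Mmp10 (1.99), mt-Tw (1.62), Gucy1a3 (1.59), mt-Ty (1.59), Zfpm1 (1.57), mt-Te (1.45), Lad1 (1.40) and Car2 (1.36). Mmp13 was at 14.95 and 1.98 RPKM in WT and 5.96 and 5.34 RPKM with the KO label. Mitochondrial tRNA genes are short, and mt-Tg rests on few reads, with 0 in the library labelled Smad4 KO at 37 °C. In all, 92 genes had a difference of at least 1 and 212 of at most −1, with a median of 0.00 over all rows. With 1 library per group this difference has no residual degrees of freedom and no test.

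Of the gene lists, the p53 and apoptosis list had the lowest median difference, −0.80 (percentile 0); beside Cdkn1a, Sesn2 was at 7.19 and 25.6 RPKM in WT and 12.1 and 16.1 RPKM with the KO label, and Bcl2 at 4.20 and 6.62, then 18.0 and 10.8 RPKM. Medians were also low for Treg genes (−0.57, percentile 0.01), core Th17 genes (−0.41, percentile 0) and pathogenic Th17 genes (−0.31, percentile 0.29). Low medians were found too for the STAT list (−0.28, percentile 0.01), ER stress genes (−0.27, percentile 0) and TGF-β and SMAD target genes (−0.25, percentile 0.22). Medians were high for heat shock genes (0.31, percentile 100), cholesterol synthesis genes (0.30, percentile 100) and histone genes (0.19, percentile 100). The Th2 (−0.36, percentile 2.35), cell cycle (−0.12, percentile 1.06) and mitochondrially encoded lists (−0.09, percentile 1.42) also lay outside the central 95% of random lists. The others lay within it: non-pathogenic Th17 (−0.01, percentile 44.6), Th1 (−0.15), Tfh (0.16, percentile 90.2), SUMO pathway (−0.03, percentile 26.5), glycolysis (−0.06, percentile 6.95), OXPHOS (−0.0032, percentile 15.3), interferon (−0.09, percentile 37.4), naive and memory (0.0016, percentile 36.2), T cell identity (−0.07, percentile 6.92), ribosomal protein (0.0031, percentile 6.13) and nuclear non-coding RNA (−0.12, percentile 21.7).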

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

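Of the tests in this part, only the one on the 19 hypoxia-inducible genes was chosen before the result it measures was seen. Its gene list was still drawn up after other results of these data had been seen. The other tests, the shorter form with 15 genes included, were chosen after. With 1 library per group the genotype cannot be separated from anything else that differed between these cultures, and the effect of Smad4 loss itself stays open as an untested biological explanation in each case.

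Smad4 was higher in both libraries labelled Smad4 KO, by a ratio of at least 1.48 (20.7 against 14.0 RPKM at 37 °C). An exchange of labels in 1 temperature pair alone is argued against, since the genotype differences at the 2 temperatures had an r of 0.71 across genes where such an exchange would turn it negative. Within the trimmed-mean and upper quartile scalings, library scaling is argued against too: the lowest Smad4 log2 ratio over both temperatures was 0.49. The trimmed-mean factors were 0.986, 0.990 and 0.990 against WT at 37 °C, so that scaling could move the ratio little. Scaling to total reads was not run. An exchange in both pairs cannot be told apart from a deletion that leaves most of the transcript, because the lower ratio of 1.48 fits either and values summed over exons do not show which exons were read.

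Heat shock genes were lower, not higher, at 39.5 °C in WT (median log2 ratio −0.26). Scaling is argued against within the same alternative scalings only, where the highest median was −0.22. Exchanged temperature labels in 1 genotype alone are argued against by an r of 0.39 between the temperature responses. An exchange in both genotypes stays open and cannot be told apart here: of 4 temperature ratios of the cold-inducible genes Cirbp and Rbm3, 1 was higher at 39.5 °C beyond counting error and 2 were lower. RNA was taken after 3 days, and an early heat shock response that had ended by then was not tested.

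Glycolysis genes were highest in the library labelled Smad4 KO at 37 °C. Their median log2 ratio to WT was 0.86 at 37 °C and 0.73 at 39.5 °C (percentile 100 in both). As the pairs share no library, a condition of the 37 °C culture alone does not account for the difference at 39.5 °C. Such a condition may still add to the values at 37 °C, which these libraries cannot settle. Scaling is argued against within the same alternative scalings only, where the lower median at 37 °C was 0.84. A candidate explanation is transcription of the hypoxia type: 19 measured hypoxia-inducible factor targets that share no gene with the glycolysis list had medians of 0.95 and 0.43 (percentile 100 in both, Bnip3 at 3.90 and 22.4 RPKM at 37 °C), and the 15 left after taking out Pfkfb3, Pfkfb4, Pgm1 and Pgm2, which encode enzymes close to glycolysis, had 1.03 and 0.71 (percentile 100 in both). Of the 19, 9 rose with the KO label over all genes and 11 when adjusted over the list alone, while with temperature 8 fell when adjusted over the list alone and 0 over all genes (median −0.05 in WT and −0.68 with the KO label, percentiles 44.0 and 0; median of the differences −0.47, percentile 0). Whether the genotype or a condition common to both cultures labelled Smad4 KO lies behind it stays open.

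Several results had temperature log2 ratios on opposite sides of 0 in the 2 genotypes, with 1 library each; this difference was not tested. For Cdkn1a, Il21 (0.79 and −0.10) and the TGF-β and SMAD targets the value with the KO label was close to 0, so these are not reversals. Nor is Hsf1, whose value in WT was close to 0 (−0.11 in WT, 0.33 with the KO label). The difference in log2 ratio, libraries labelled Smad4 KO minus WT, was −3.01 for Cdkn1a (2.94 in WT, −0.07 with the KO label), −2.75 for Basp1 and −2.69 for Ndrg1. It was −0.89 for Il21, 0.43 for Hsf1, 1.36 for Car2, 1.57 for Zfpm1 and 1.59 for the mitochondrial tRNA gene mt-Ty. Among the lists the median of the members' differences was −0.28 for the STAT list (medians 0.14 in WT and −0.29 with the KO label). It was −0.25 for the TGF-β and SMAD targets (0.14 and −0.01).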

How the results depend on the processing

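The agreement of the temperature and of the genotype comparisons kept its reading under each alternative run. So did the number of list medians outside the central 95% (65 of 120). The 2-fold counts kept theirs under both rescalings and without a filter. The other counts moved by more than 1.5 times. Total genes past the rule, in the order temperature in WT (272), temperature with the KO label (228), genotype at 37 °C (801), genotype at 39.5 °C (459) and difference between genotypes (304), were 1087, 976, 2584, 2118 and 1347 at 1.5-fold, 556, 458, 1220, 866 and 628 with a pseudocount of 0.1, 74, 69, 332, 140 and 75 with a pseudocount of 5, and 144, 104, 512, 273 and 129 at a mean of at least 5 RPKM. A looser rule or smaller pseudocount admits more genes by construction, and a higher minimum leaves fewer to count. Genes with a shared temperature change (3) numbered 92 after trimmed-mean rescaling, 30 with a pseudocount of 0.1, 290 at a mean of at least 5 RPKM, 350 with limma-voom on recovered reads (chosen after seeing the data), and 0 without a trend, 0 without a filter and 0 with a pseudocount of 5, where the smallest adjusted p were 0.059, 0.283 and 0.121 and 1885, 2270 and 1840 genes had an unadjusted p under 0.05. The 3 genes were among those called in every setting that called any. Genes with a shared genotype change (1820) numbered 2894 with limma-voom, 1693 of them shared, and 0 without a filter, where 5396 genes had an unadjusted p under 0.05; the cause was not tested. Their split into 1176 rising and 644 falling became 1054 and 798 with the upper quartile, where genes at unadjusted p under 0.05 turned from 2603 higher and 2145 lower to 2318 and 2507, and 1620 and 1274 with limma-voom. The call of Smad4 ended without a trend, without a filter and with the upper quartile. The Th1 list reversed at a mean of at least 5 RPKM, to −0.18 in WT and −0.53 with the KO label, where fewer members are left, and the Itga7 difference between genotypes became 0.10 with a pseudocount of 0.1. Of the list medians, 335 values over all alternatives kept direction and side of the threshold, 9 newly passed and 9 no longer did; of named genes, 1526 ratios kept them, 30 newly passed, 63 no longer did and 1 reversed, and 1011 shared changes kept them, 134 newly passed and 65 no longer did. No paired analysis was possible because each group had 1 library and no replicate numbers to pair on beyond genotype and temperature, which the additive fit already holds. Leaving out a library would leave the additive fit no residual degrees of freedom. The tests set out for deposited counts were not run on the RPKM values, and limma-voom was the only test run on recovered reads. Il22, under 1 RPKM in each library, fell below the minimum mean, so the main fit did not test it.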

Other observations

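3 genes of antigen presentation, picked after their values were seen because they differed, were higher with the KO label. H2-Ab1, the gene of an MHC class II β chain, stood at 4.56 and 3.23 RPKM in WT at 37 and 39.5 °C and at 59.6 and 19.3 RPKM in the libraries labelled Smad4 KO. H2-DMa was at 4.88 and 4.36 RPKM in WT and 24.7 and 28.9 RPKM with the KO label. The invariant chain gene Cd74 was at 12.7 and 22.6 RPKM in WT and 23.3 and 41.7 RPKM with the KO label. No list was fixed for these genes, so they say nothing of antigen presentation genes as a group, and whether they came from T cells or from other cells was not tested.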
